A study of Homo sapiens with 12 samples.

How the data were processed

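Transcript levels were measured by RNA sequencing of total RNA in 12 libraries, 3 for each combination of 2 prostate cancer lines (DU145, PC3) and 2 GFP sorts (brightest and dimmest 10%). Per the labels' protocols, cells grew in DMEM with 10% serum and RNA was extracted with a column kit. The submitters' processing notes name STAR and DESeq2, without versions; the genome build and the counting method are not given in the sources used here. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or sorts, so p-values measure only the spread between these samples, which may be technical. Samples were assigned to groups by their labels.

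The deposited table, per the labels log2 normalized counts, gives genes under Ensembl identifiers with symbols, and all of its 12 columns were used. The values themselves showed how the authors had scaled them. The lowest value of each column was shared by many genes, and the next step lay where 1 count added to an offset of 0.5 would fall, so the deposited log2 values were read as log2 CPM, that is, of the count + 0.5 over a scaled library total. Undoing this gave estimated counts, of which 86.9% (median library) were whole within 0.01, the rest being fractional. CPM values printed here are the deposited values taken out of the log2 scale and include that offset. Mitochondrially encoded genes were not in the table.

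The design had been fixed on the assumption of log2(normalized count + 1). Because the scale is CPM instead, the fixed minimum (log2 value of at least 4 in at least 3 of the 12 samples) meant 16 CPM and kept 8655 genes. It was applied as fixed. Genes fixed by name that lay below it are reported from the planned fit to all genes of the table, and a minimum of 0 in log2 was added as an alternative after seeing the data.

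Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with 4 group means over the 12 samples, 8 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment within each contrast at 0.05. The contrasts were GFP high against low in DU145, in PC3, the mean of both, their difference, and DU145 against PC3. On simulated data built from these line means, gene spreads and library sizes over 8655 genes, with 200 changed genes per line, the DU145 comparison recovered 75.9% of genes changed 1.5-fold, 98.3% of those changed 2-fold and 100% of those changed 4-fold, with 4.28% false calls. The PC3 comparison recovered 78.5%, 90.9% and 100%, with 4.79% false calls. The simulated spread was independent between genes and held no library-wide trend in GC content or length. The real libraries had such a trend, so these rates of false calls do not carry over to the real counts.

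Before the data were examined, 33 gene lists (816 entries, 779 found) were fixed, and the 27 with at least 3 genes above the minimum were tested with camera at a correlation of 0.01. Alternatives were camera with an estimated correlation and fry, which tests a list against no change and not against the other genes. The named genes follow a rule fixed at the same time. For each line it takes the 8 largest rises and 8 largest falls among genes past the threshold, with non-overlapping groups and a mean log2 value of at least 5. It adds the 6 genes risen and 6 fallen in both lines with the largest smaller change, the 4 most positive and 4 most negative differences between lines (same mean minimum), up to 4 members of each list described with the smallest p, and 12 Wnt genes always. Genes without a symbol, clone names and Y-linked genes were passed over. Some genes that this rule takes are not reported here. Genes chosen outside the rule are named as such.

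Replicate numbers are shared between the sorts of a line. Deviations of same-numbered PC3 libraries from their group means correlated at 0.12, 0.43 and 0.35, all above 0.1. The numbers were therefore taken to pair the PC3 libraries, from the data and not from the labels. Differently numbered libraries reached 0.117 for replicate 1 and 0.137 for replicate 3, so this pairing is uncertain. In DU145 the numbers did not pair the libraries. Alternatives fixed beforehand were the replicate block, no minimum, a minimum of 6, equal medians, quantile normalization, eBayes without trend or with robust estimation, arrayWeights, each line alone, voom on the estimated counts, a 2-fold threshold, an adjusted p under 0.01 and leaving out each library. Added after seeing the data were an offset of 8 counts, removal of the trend in GC content and transcript length (loess per library against its line's mean, span 0.4) with and without the replicate block, and leaving out PC3 GFP low replicates 2 and 3 or DU145 GFP high replicates 1 and 2. GC content, length and positions came from GENCODE 29 on GRCh38, matched by identifier for 18901 genes (8651 of those kept).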

Results

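RNA was sequenced from DU145 and PC3, 2 established human prostate cancer cell lines, after each line had been sorted by the intensity of a green fluorescent protein (GFP). Per the labels, the brightest 10% of the cells were collected as cells with active Wnt/β-catenin signaling and the dimmest 10% as cells with inactive signaling. The 12 libraries formed 4 groups of 3 (DU145 GFP high, DU145 GFP low, PC3 GFP high and PC3 GFP low). The total estimated count ranged from 13453614 in DU145 GFP high replicate 3 to 21528810 in PC3 GFP high replicate 3. Libraries of the same group differed by 5.76 to 42.6 times the variance that sampling alone would give, so none was a second deposit of another. Levels are given in CPM (counts scaled to a common library total, taken from the deposited log2 CPM) as mean ± SD of 3 libraries unless another n is stated, and log2 fold changes are GFP high over GFP low with their standard error. At a total of this size, a count of 0 allowed a level of up to 0.233 CPM in the shallowest library, and such limits cover counting error only.

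The first question was whether known Wnt target genes differed between the sorted populations. LEF1 (ENSG00000138795, chromosome 4, 108047545 to 108168956 in the GRCh38 annotation), a transcription factor that acts with β-catenin and is itself a Wnt target, rose in GFP high cells of both lines. In DU145 it stood at 2.21 ± 0.30 CPM in GFP high and 0.642 ± 0.265 CPM in GFP low (log2 fold change 1.87 ± 0.40, limma adjusted p = 0.00959, 95 against 29 estimated counts). In PC3 it stood at 4.41 ± 0.64 CPM and 1.43 ± 0.44 CPM (1.67 ± 0.40, limma adjusted p = 0.022, 278 against 72 estimated counts). These LEF1 values come from the fit to all genes of the table, because LEF1 lay below the expression minimum of 16 CPM. The PC3 call was lost when any 1 of the 3 PC3 GFP high libraries or PC3 GFP low replicate 2 was left out, and the highest adjusted p over the alternatives was 0.283. The DU145 call was lost when that line was fitted alone (adjusted p = 0.0606) and when DU145 GFP high replicates 1 and 2 were both left out (0.168).

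**Figure D1:**
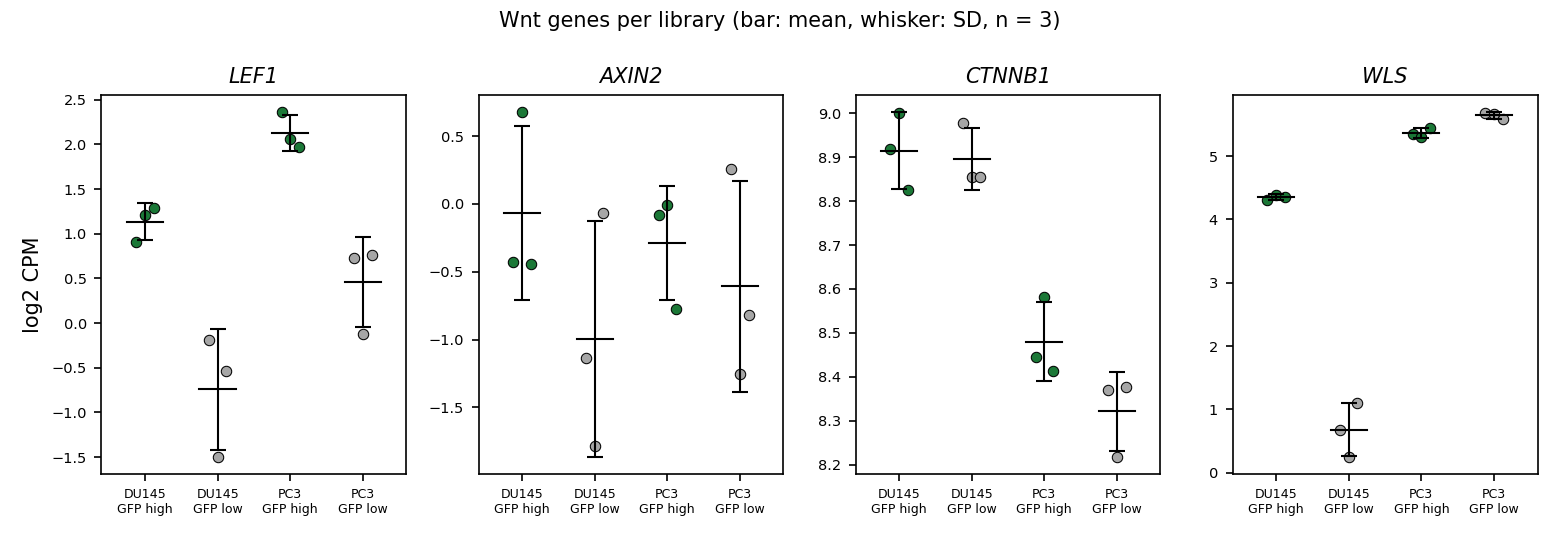
Level of LEF1, AXIN2, CTNNB1 and WLS in each of the 12 libraries, in log2 CPM on an axis of its own for each gene, with 1 point per library, a bar at the group mean and a whisker of 1 SD (n = 3; green, GFP high; grey, GFP low). LEF1 of every GFP high library lay above that of every GFP low library of its line, whereas the AXIN2 ranges overlapped.

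AXIN2, a negative feedback gene of the pathway, did not pass the test in either line. It had 45 estimated counts in DU145 GFP high and 25 in GFP low (log2 fold change 0.93 ± 0.58, adjusted p = 0.304), and 51 against 36 in PC3 (0.32 ± 0.58, adjusted p = 0.814). NKD1, RNF43, TCF7, NOTUM, SP5 and DKK1 did not pass in either line with all genes fitted, with adjusted p-values of at least 0.137. LGR5 had 0 counts in the DU145 libraries and 1 count in the PC3 libraries, so a difference was not detectable at this depth. ZNRF3 (adjusted p = 0.0612 in DU145 and 0.635 in PC3), CTNNB1, which encodes β-catenin (0.847 and 0.22), and TCF7L2 (0.494 and 0.608) were above the minimum and did not pass either.

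As a group, the Wnt lists did not stand apart from the other genes. Of 30 Wnt feedback targets, 27 were measured without a minimum. In DU145, 1 of them rose, 1 fell and 25 did not pass (camera adjusted p = 0.779), and in PC3, 1 rose and 26 did not pass (adjusted p = 0.693). Adjusted over the list alone, the same numbers passed. The feedback target that fell in DU145 was KREMEN1, which lay above the minimum (log2 fold change -0.55 ± 0.11, limma adjusted p = 0.00505). Its estimates ranged from -0.61 to -0.39 over the alternatives. In PC3 it did not pass (0.24 ± 0.11, limma adjusted p = 0.207). Among the 18 other reported Wnt targets above the minimum, 2 rose and 6 fell in DU145 (camera adjusted p = 0.321; 2 and 6 adjusted over the list alone). MYC fell (log2 fold change -0.47 ± 0.06), VCAN fell (-0.91 ± 0.13) and MET, a receptor tyrosine kinase, rose (0.73 ± 0.13). In PC3, 2 rose and 2 fell (camera adjusted p = 0.958; 2 and 3 adjusted over the list alone), with SOX9 at -0.37 ± 0.10, CCND1 at 0.22 ± 0.06 and CD44 at -0.21 ± 0.06, each of which lost its call when any 1 of several libraries was left out. Among 29 Wnt pathway components, 5 rose and 3 fell in DU145 (camera adjusted p = 0.571; 5 and 3 adjusted over the list alone) and 2 rose and 5 fell in PC3 (0.894; 3 and 5 adjusted over the list alone). WLS, the carrier needed for secretion of Wnt ligands, rose in DU145 from 1.65 ± 0.47 to 20.4 ± 0.6 CPM (log2 fold change 3.67 ± 0.17, limma adjusted p = 2.81e-08), while it did not pass in PC3 (-0.28 ± 0.17, adjusted p = 0.371). The Wnt receptor genes FZD6 and FZD8 changed in opposite directions in DU145 (1.41 ± 0.20 and -1.92 ± 0.20). The DU145 calls of MET (adjusted p = 0.252) and FZD6 (0.0547) were lost without both GFP high replicates 1 and 2. In PC3, DKK3 fell (-0.61 ± 0.07), and the corepressor gene TLE2 fell (-2.93 ± 0.54) at a level of 5 against 30 estimated counts.

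In DU145, the question was which genes differed between GFP high and GFP low cells. Among genes with a mean log2 CPM of at least 5 in that line, the largest rises were in XPO4, a nuclear transport receptor gene (ENSG00000132953, chromosome 13, 20777329 to 20903048), which went from 23.7 ± 1.5 to 293 ± 50 CPM (12.3-fold, log2 fold change 3.62 ± 0.13, limma adjusted p = 2.96e-09), in the deubiquitinase gene USP3 (36.2 ± 3.1 to 210 ± 25 CPM, 5.78-fold) and in HSPG2, which encodes the basement membrane proteoglycan perlecan (50.7 ± 1.4 to 228 ± 3 CPM, 4.49-fold). The histone methyltransferase gene KMT2C rose 4.19-fold, the cytokine gene LTB 2.98-fold and the desmosomal cadherin gene DSG2 2.79-fold. The histone genes HIST2H4A and HIST1H2BK rose 3.34-fold and 2.58-fold. TNF fell from 119 ± 8 to 43.1 ± 2.6 CPM (log2 fold change -1.47 ± 0.12), and PHLDA2 (-1.36 ± 0.14), CBSL (-1.03 ± 0.10), EEF1A2 (-0.93 ± 0.19), the metalloproteinase inhibitor gene TIMP2 (-0.92 ± 0.29), PDLIM1 (-0.89 ± 0.12) and the metalloproteinase gene MMP15 (-0.87 ± 0.23) also fell. The GFP high and GFP low libraries did not overlap for any of these genes, as the rule for naming them required. The calls of TIMP2 and MMP15 were lost when 1 of several DU145 libraries was left out, and that of LTB without GFP high replicate 2. That of TIMP2 was also lost with the trend in GC content and transcript length removed. Those of HIST2H4A, EEF1A2 and PDLIM1 were lost without both GFP high replicates 1 and 2. HIST2H4A and CBSL had fractional estimated counts in all 12 libraries, and each has a near-identical copy, so their values are uncertain. USP3, HSPG2 and TIMP2 had fractional counts in some libraries, so their values are less certain too. WDR63 and KIAA1324, chosen after their values were seen, had 1497 and 2665 estimated counts in DU145 GFP high and 6 and 22 in DU145 GFP low. In 2 of the 3 GFP low libraries WDR63 had 0 counts, so the size of its change rests on the offset.

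In total, 3133 of 8655 genes passed in DU145 (limma, adjusted p under 0.05), 1339 higher and 1794 lower in GFP high. The excess of lower genes depended on the scaling, with 1471 higher and 1342 lower at equal medians and 807 and 852 after quantile normalization. Of the 3133, 118 were higher and 31 lower by at least 2-fold. The size of this set rested on single libraries. It was 865 without DU145 GFP high replicate 1, 1042 without GFP high replicate 2, 4928 without GFP high replicate 3, 1263 without GFP low replicate 1 and 871 without GFP low replicate 3. The log2 fold changes also followed GC content across genes (Spearman rho -0.71, genes not being independent replicates), with a median of 0.46 in the 20% of genes poorest in GC and -0.27 in the 20% richest. With the trend in GC content and transcript length removed, 2248 genes passed, and 587 of the higher and 873 of the lower calls were shared. Without GFP high replicates 1 and 2, 126 genes passed.

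Among the lists fixed beforehand, 4 of 27 stood apart in DU145 (camera, preset correlation of 0.01), and none did with an estimated correlation. Of 10 ways to split the DU145 libraries into groups of 3, the real split included, 3 gave at least as many lists. Replication-dependent histone genes rose. Of 24, 5 were above the minimum, 4 of which rose and 1 fell (camera adjusted p = 0.0153, adjusted p = 0.746 with an estimated correlation), among them HIST1H2AC (1.35 ± 0.16) and HIST1H1C (1.13 ± 0.15). Without a minimum, 14 of 24 rose and 1 fell (17 rose and 1 fell adjusted over the list alone, adjusted p = 0.0432 with an estimated correlation). Cholesterol synthesis genes were lower, with 12 of 24 fallen and 1 risen (12 and 3 adjusted over the list alone; camera adjusted p = 0.0354, adjusted p = 0.746 with an estimated correlation). DHCR7, which carries out a final step of the synthesis, fell by 0.59 ± 0.09 and MVD by 0.70 ± 0.12 on the log2 scale. Hypoxia and glycolysis genes were lower, with 14 of 24 fallen and 2 risen (16 and 2 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.746 with an estimated correlation), including the hexokinase genes HK1 (-0.59 ± 0.10) and HK2 (-0.40 ± 0.09). Of 59 ribosomal protein genes, 12 fell and none rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.0153, adjusted p = 0.749 with an estimated correlation), with RPS15 at -0.42 ± 0.12 and RPL8 at -0.40 ± 0.13, both of which lost their calls when 1 of several DU145 libraries was left out. The ribosomal call was lost with the GC and length trend removed (adjusted p = 0.0568) and without DU145 GFP high replicate 1 (0.0752) or 2 (0.0765). The histone call was lost without DU145 GFP high replicate 3 (0.0769), and the cholesterol call without that library (0.0865) or DU145 GFP low replicate 2 (0.0859). Without both DU145 GFP high replicates 1 and 2, the hypoxia and glycolysis list was at 0.0705, and the calls of HK1 (0.181), HK2 (0.0568), MVD (0.183) and DHCR7 (0.0982) were lost.

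**Figure D2:**
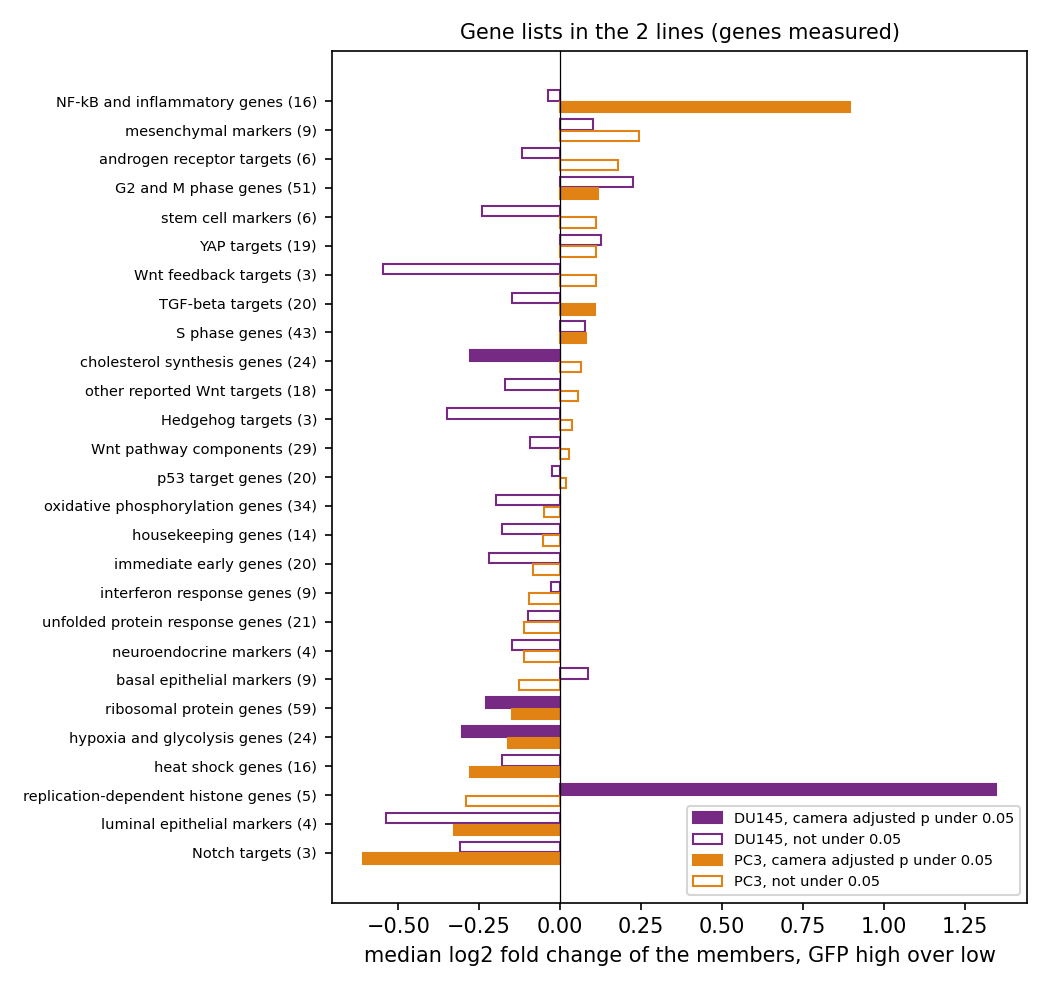
Median log2 fold change, GFP high over low, of the measured members of each of the 27 tested gene lists in DU145 (purple) and PC3 (orange), with the number of measured genes in brackets. Filled bars mark a camera adjusted p under 0.05. The longest filled bars are those of replication-dependent histone genes in DU145 (1.35) and of NF-kB and inflammatory genes in PC3 (0.89).

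In PC3, the genes named for the same comparison again had a mean log2 CPM of at least 5. EFNA1, an ephrin ligand gene, rose from 25.8 ± 4.3 to 106 ± 17 CPM (4.12-fold, log2 fold change 2.04 ± 0.13, limma adjusted p = 5.15e-07), and the gap junction gene GJA1 rose from 46.2 ± 5.9 to 181 ± 5 CPM (3.94-fold). The chemokine genes CXCL1 and CXCL8 rose 2.97-fold and 2.93-fold, and the complement gene C3 (2.24-fold), LSR (2.27-fold), STC2 (2.19-fold) and CITED2 (2.04-fold) rose as well. SEC24B, a gene of the COPII vesicle coat, fell from 245 ± 35 to 38.2 ± 2.0 CPM (log2 fold change -2.67 ± 0.13, limma adjusted p = 3.51e-08). TRNP1 (-1.49 ± 0.13), the calcium-binding protein gene S100A6 (-1.44 ± 0.15), BTBD2 (-1.40 ± 0.16), the polymerase delta subunit gene POLD4 (-1.25 ± 0.15), AK4 (-1.24 ± 0.11), the histone demethylase gene KDM4A (-1.15 ± 0.07) and the phosphofructokinase gene PFKL (-1.10 ± 0.10) fell. AK4 had fractional estimated counts in all 12 libraries, and BTBD2, POLD4 and KDM4A in some, so their values are uncertain. The call of GJA1 was lost without both PC3 GFP low replicates 2 and 3 (adjusted p = 0.0753).

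In total, 867 of 8655 genes passed in PC3, 380 higher and 487 lower, of which 59 and 67 differed by at least 2-fold. The balance turned to 402 higher and 360 lower at equal medians and 541 and 516 after quantile normalization. The count was 462, 464 and 553 without GFP high replicates 1, 2 and 3 and 541 without GFP low replicate 1. Removing the GC and length trend raised it to 2082, 1100 higher and 982 lower (2334 in all with the replicate block), sharing 369 of the higher and 476 of the lower calls. Of all replicate pairs, GFP low replicates 2 and 3 had the largest variance over sampling (42.6 times). By correlation, DU145 GFP high replicates 1 and 3 differed more (0.971, against 0.973). Without both PC3 GFP low replicates 2 and 3, which left a lone library in that group, fewer genes passed.

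NF-kB and inflammatory genes rose together in PC3. Of 16 members above the minimum, 14 rose and none fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 0.89 (camera adjusted p = 1.9e-23, adjusted p = 0.00366 with an estimated correlation). CCL2, a monocyte chemoattractant gene, went from 1.63 ± 0.22 to 18.4 ± 0.8 CPM (11.3-fold, log2 fold change 3.50 ± 0.16). This was 1 of 9 lists that stood apart, and the call that held with an estimated correlation. Heat shock genes were lower, with 5 of 16 fallen and none risen (8 and 0 adjusted over the list alone; camera adjusted p = 0.000309, adjusted p = 0.178 with an estimated correlation), including the collagen chaperone gene SERPINH1 (-0.81 ± 0.08) and HSPB1 (-0.64 ± 0.14). Of 24 hypoxia and glycolysis genes, 4 fell and none rose (4 and 0 adjusted over the list alone; 0.00249, adjusted p = 0.405 with an estimated correlation), including DDIT4 (-1.22 ± 0.17) and BNIP3 (-0.48 ± 0.08). Of 51 G2 and M phase genes, 4 rose and none fell (4 and 0 adjusted over the list alone; 0.00244, adjusted p = 0.364 with an estimated correlation), including KIF2C (0.35 ± 0.07) and NCAPD2 (0.28 ± 0.07). The calls of KIF2C and HSPB1 were lost without PC3 GFP high replicate 2. Those of RRM2 and NCAPD2 were lost without any 1 of 4 of the 6 PC3 libraries and when the line was fitted alone. Without both PC3 GFP low replicates 2 and 3, the calls of all 4 genes and that of BNIP3 were lost. Of 43 S phase genes, 1 rose, RRM2 (0.30 ± 0.08), and 42 did not pass (none adjusted over the list alone; 0.0408, adjusted p = 0.466 with an estimated correlation). Of 59 ribosomal protein genes, none passed by itself (0 adjusted over the list alone), with a list median of -0.15 (0.00184, adjusted p = 0.686 with an estimated correlation). RPS13 had a log2 fold change of -0.28 ± 0.09 (adjusted p = 0.0796, and 0.0285 with the replicate number as a block) and RPS23 of -0.24 ± 0.09. Without PC3 GFP low replicate 2, the adjusted p of the ribosomal, G2 and M phase and S phase lists was 0.318, 0.104 and 0.232. The S phase call was also lost without PC3 GFP high replicate 1 (0.081). Without both PC3 GFP low replicates 2 and 3, the G2 and M phase list was at 0.0568 and the S phase list at 0.348.

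A further 3 lists passed in PC3 and did not pass with the replicate number as a block. Of 20 TGF-beta targets, 5 rose and 3 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.0408, 0.0731 with the block, adjusted p = 0.318 with an estimated correlation). The basement membrane collagen genes COL4A1 and COL4A2 rose 6.55-fold and 6.49-fold, to 32.3 ± 0.3 and 65.4 ± 1.6 CPM. Of 3 Notch targets, 2 fell (2 adjusted over the list alone; 0.0443, 0.0632 with the block, adjusted p = 0.318 with an estimated correlation), namely JAG2 (-1.05 ± 0.11), which encodes a Notch ligand, and GPR161 (-0.61 ± 0.13). Of 4 luminal epithelial markers, 2 fell (2 adjusted over the list alone; 0.0443, 0.0552 with the block, adjusted p = 0.466 with an estimated correlation), the tetraspanin gene CD9 (-0.69 ± 0.08) and the keratin gene KRT8 (-0.53 ± 0.10). All 3 calls were lost without PC3 GFP high replicate 1 (adjusted p = 0.052 for TGF-beta targets and 0.053 for the others). The Notch call was also lost without PC3 GFP low replicate 2 (0.104) or 3 (0.0826), and the luminal call without PC3 GFP low replicate 2 (0.206) or PC3 GFP high replicate 3 (0.0566). The calls of GPR161 and KRT8 were lost without both PC3 GFP low replicates 2 and 3. Without a minimum, the Notch list was at 0.383 and the luminal list at 0.0787. The list named Notch targets also held genes of Notch ligands and receptors, so its fall is not a measure of Notch target activity.

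The lines were then asked for genes that moved the same way in both. FN1, which encodes fibronectin, rose in both, from 1.17 ± 0.27 to 5.58 ± 0.54 CPM in DU145 (4.84-fold) and from 4.78 ± 0.78 to 49.5 ± 2.5 CPM in PC3 (10.4-fold). CALD1 (1.96-fold and 2.16-fold), the insulin-like growth factor binding protein gene IGFBP3 (1.76-fold and 2.71-fold), RAB3B (1.52-fold and 2.68-fold) and HSPG2 (4.49-fold and 1.55-fold) also rose in both. ALDH1A1, an aldehyde dehydrogenase gene, fell in both, by 1.58 ± 0.30 on the log2 scale in DU145, where it had 5 against 18 estimated counts, and by 1.56 ± 0.30 in PC3 (46.6 ± 3.6 to 15.8 ± 1.4 CPM). ADGRG1 (-0.95 ± 0.29 and -1.52 ± 0.29), EEF1A2 (-0.93 ± 0.19 and -0.82 ± 0.19), GFPT2 (-0.87 ± 0.21 and -0.80 ± 0.21), SERPINE2 (-0.90 ± 0.09 and -0.78 ± 0.09) and PDLIM1 (-0.89 ± 0.12 and -0.71 ± 0.12) fell in both. In PC3, the call of GFPT2 was lost without any 1 of the 6 PC3 libraries, and that of EEF1A2 without GFP high replicate 2 or GFP low replicate 1. The call of ALDH1A1 was lost in DU145 when that line was fitted alone (adjusted p = 0.0706), where its fall also shrank to -0.42 with an offset of 8 counts, and in PC3 without both GFP low replicates 2 and 3 (0.163). CALD1, IGFBP3 and RAB3B lost their DU145 calls without both GFP high replicates 1 and 2, and IGFBP3 also with quantile normalization (estimates from 0.42 to 0.96 over the alternatives). ADGRG1 lost its PC3 call without both GFP low replicates 2 and 3 (0.115). In DU145, the call of ADGRG1 was lost when 1 of several libraries was left out and with the GC and length trend removed, and its log2 fold change went to -0.52 without GFP high replicate 2. There, the call of GFPT2 was lost without GFP low replicate 3. The calls of GFPT2 and ADGRG1 in DU145 and of EEF1A2 in PC3 were also lost when the line was fitted alone and with voom.

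For the mean effect over both lines, 1735 genes passed, 597 higher and 1138 lower. Setting all libraries to equal medians gave 771 higher and 714 lower, and quantile normalization 667 and 750. The count was 726 without DU145 GFP low replicate 3, 792 and 795 without DU145 GFP high replicates 2 and 1, 910 without DU145 GFP low replicate 1, 879 and 942 without PC3 GFP high replicates 3 and 1, 1043 without PC3 GFP low replicate 2, 2787 without PC3 GFP low replicate 3 and 3958 without DU145 GFP high replicate 3.

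Across the 8655 genes, the log2 fold changes of the 2 lines were nearly uncorrelated (Pearson r = 0.023, Spearman rho = 0.053, genes not being independent replicates). Genes higher in both numbered 28, against 58.8 for independent lists, and genes lower in both 105, against 101. Genes lower in DU145 and higher in PC3 numbered 118, against 78.8, and those with the opposite pattern 35, against 75.3. The shortfall of genes higher in both and the excess of genes lower in DU145 and higher in PC3 kept their direction in 2 alternatives, while the other 2 patterns did not. With the GC and length trend removed, the numbers in the same order were 106 against 120, 108 against 148, 263 against 165 and 157 against 107. Without a minimum they were 24 against 35, 80 against 48.1, 95 against 36.4 and 35 against 46.3. Pearson's r was -0.20 without PC3 GFP low replicate 2 and 0.18 without PC3 GFP low replicate 3.

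**Figure D3:**
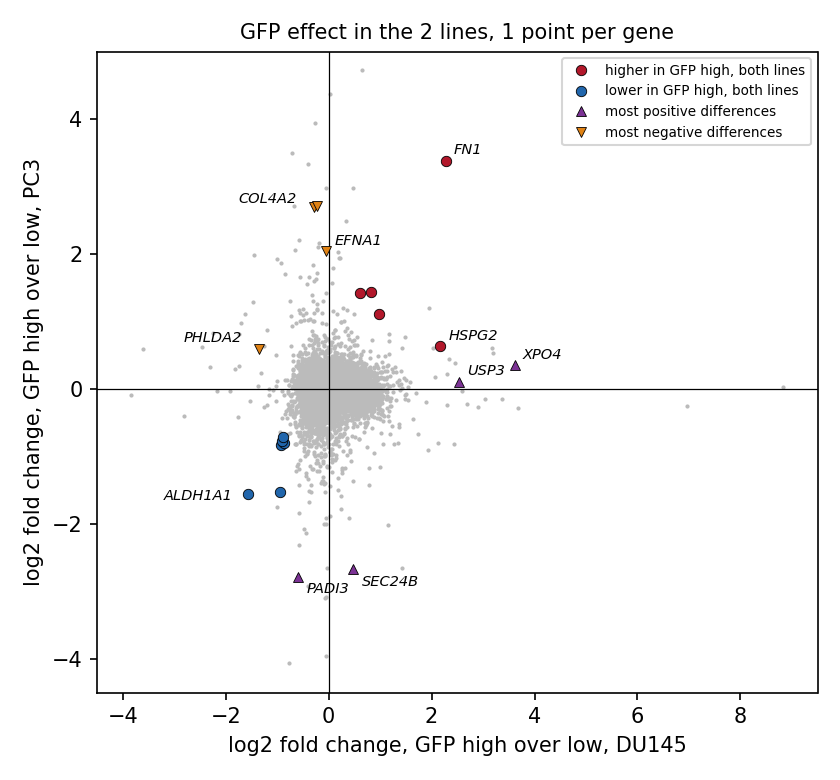
Log2 fold change, GFP high over low, in DU145 (horizontal axis) against PC3 (vertical axis), with 1 grey point for each of 8655 genes. Red and blue circles mark the genes named as higher or lower in both lines, and triangles those with the most positive (upward) or most negative (downward) difference between the lines among genes with a mean log2 CPM of at least 5 over all libraries. FN1 lies at 2.28 and 3.38, XPO4 at 3.62 and 0.35.

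The difference between the lines was tested as such. Among genes with a mean log2 CPM of at least 5 over all 12 libraries, XPO4 (difference in log2 fold change 3.27 ± 0.19), SEC24B (3.15 ± 0.19), USP3 (2.42 ± 0.14) and PADI3 (2.19 ± 0.17) had the most positive differences. PADI3, a peptidylarginine deiminase gene, fell in both lines, more in PC3 (-2.78 ± 0.12) than in DU145 (-0.59 ± 0.12). COL4A2 (-2.99 ± 0.14), COL4A1 (-2.93 ± 0.14), EFNA1 (-2.09 ± 0.19) and PHLDA2 (-1.96 ± 0.19) had the most negative ones. Below that minimum, WLS (3.95) and CCL2 (-4.21) differed more. TNF, which also lay below that minimum over all libraries, fell in DU145 and rose in PC3 (1.29 ± 0.12), a difference of -2.75 ± 0.17. In total 1667 genes passed, 640 with a more positive effect in DU145 and 1027 with a more positive effect in PC3. With the replicate number as a block, the balance was nearly even, at 1435 and 1485 of 2920 genes. Of the 27 lists, 3 differed. NF-kB and inflammatory genes had 14 of 16 members with a more positive effect in PC3 (15 adjusted over the list alone; camera adjusted p = 4.53e-12, adjusted p = 0.0334 with an estimated correlation). For cholesterol synthesis genes this held for 11 of 24, with 1 the other way (12 and 1 adjusted over the list alone; 0.0123, adjusted p = 0.511 with an estimated correlation). Of 5 histone genes, 4 had a more positive effect in DU145 (4 adjusted over the list alone; 0.00655, adjusted p = 0.324 with an estimated correlation). The count of 1667 was 948 and 971 without DU145 GFP low replicates 1 and 3, 1046, 1057 and 3207 without DU145 GFP high replicates 1, 2 and 3, 1071 and 967 without PC3 GFP high replicates 1 and 2, and 976, 2947 and 1074 without PC3 GFP low replicates 1, 2 and 3.

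**Figure D4:**
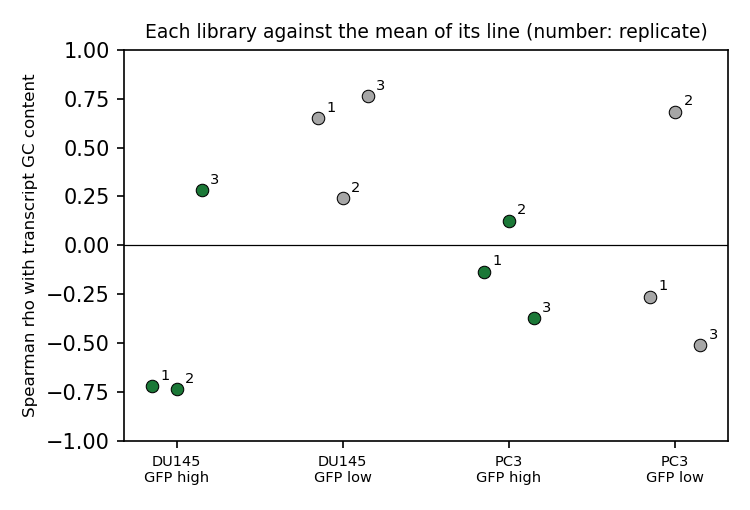
Spearman correlation, across genes, between transcript GC content and each library's deviation from the mean of its cell line (vertical axis, no unit), with 1 point per library in its group (horizontal axis) and the replicate number beside it. DU145 GFP high replicates 1 and 2 lie at -0.72 and -0.74 and replicate 3 at 0.28, and PC3 GFP low replicates 2 and 3 lie at 0.68 and -0.51.

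The lines themselves differed in 6849 of 8655 genes over both sorts (limma), 3406 higher in DU145 and 3443 higher in PC3. KRT8 stood at 2254 ± 572 CPM in DU145 and 22.1 ± 4.8 in PC3 (mean ± SD of 6 libraries, as for the values that follow), and the neuronal cadherin gene CDH2 at 3.47 ± 2.78 and 72.1 ± 10.7. CTNNA1, which encodes α-catenin and which PC3 is known to have lost by deletion, stood at 398 ± 17 CPM in the PC3 libraries, against 461 ± 34 in DU145. The epithelial genes CDH1 and EPCAM, known to be expressed in DU145, had 29 and 5 estimated counts over the 6 DU145 libraries and 5 and 4 over the 6 PC3 libraries. CDH1, EPCAM, CDH2 and KRT8 between the lines were chosen after their values were seen.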

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

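Tests on GC content, the GC test of neighbouring runs and both tests on CTNNA1 were chosen after the results they concern had been seen. The effect of the GFP sort differed between the lines for 1667 genes, by the test of the difference itself (limma, adjusted p under 0.05). Differences are log2 fold change in DU145 minus that in PC3. Among the named genes, positive differences were found for WDR63 (8.81), KIAA1324 (7.23), WLS (3.95), XPO4 (3.27), SEC24B (3.15), TLE2 (2.53), USP3 (2.42), HIST2H4A (2.40), PADI3 (2.19), HIST1H2AC (2.14), HIST1H2BK (1.93), KMT2C (1.89), TRNP1 (1.67), DSG2 (1.57), HSPG2 (1.54), POLD4 (1.51), S100A6 (1.45), HIST1H1C (1.42), FZD6 (1.34), BTBD2 (1.32), AK4 (1.30), KDM4A (1.12), MET (1.03), PFKL (0.90), JAG2 (0.83), DKK3 (0.72), SERPINH1 (0.53) and BNIP3 (0.46). WDR63 had 0, 0 and 6 counts in the DU145 GFP low libraries, so its difference is not exact, and it ranged from 5.95 to 10.1 over the alternatives, that of KIAA1324 from 6.23 to 8.73 and that of TLE2 from 0.80 to 3.06.

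Negative differences were found for CCL2 (-4.21), GJA1 (-3.42), COL4A2 (-2.99), COL4A1 (-2.93), TIMP2 (-2.78), TNF (-2.75), EFNA1 (-2.09), CXCL8 (-1.98), PHLDA2 (-1.96), FZD8 (-1.90), CXCL1 (-1.51), LSR (-1.42), CITED2 (-1.40), STC2 (-1.27), FN1 (-1.11), CBSL (-0.85), RAB3B (-0.82), C3 (-0.81), KREMEN1 (-0.79), DHCR7 (-0.76), MVD (-0.73), KIF2C (-0.66), RRM2 (-0.61), NCAPD2 (-0.58), HK1 (-0.53), MCM4 (-0.51), BCL9L (-0.45) and MYC (-0.37). The differences of TLE2, HK1 and FN1 lost their calls when 1 of several libraries was left out. That of MYC lost its call with quantile normalization and with the GC and length trend removed (-0.39 to -0.16 over the alternatives, highest adjusted p 0.192), and that of MCM4 with quantile normalization (0.122). Without both DU145 GFP high replicates 1 and 2 the calls of KREMEN1, FZD6, MVD, BCL9L and SERPINH1 were lost, and without both PC3 GFP low replicates 2 and 3 those of RAB3B and BNIP3. The median difference was -1.09 for NF-kB and inflammatory genes, -0.38 for cholesterol synthesis genes and 1.93 for histone genes. TNF, TIMP2, GJA1, CXCL8, CCL2, PHLDA2, CITED2, RRM2, KIF2C, NCAPD2, SEC24B, COL4A2 and HIST1H2AC passed in both lines with opposite signs. For TIMP2, the DU145 call was lost with the GC and length trend removed.

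Other splits of the same libraries were fitted to see whether chance could be excluded. In DU145 (3133 genes, highest other split 0) and in PC3 (867 genes, highest other split 0), 10 splits are too few for a share under 0.05, and each of these counts was reached by 1 split, the real one. In PC3, 4 splits part all 3 pairs, which is also too few. For the lists in DU145, the 4 called were reached by 3 of 10 splits (highest other 7), so chance was not excluded. The 9 lists in PC3 were reached by 1 split, the real one (highest other 7, median of the others 3), and 10 splits are again too few. For the mean over both lines, 1 of 100 drawn splits, the real one, reached 1735 genes, and for the difference 2 of 100 reached 1667. For both, this excludes only a chance division of these 12 libraries, with sort labels that mean nothing in either line. The counts cannot tell a shared effect from a line-specific effect. Chance between cultures or sorts was not covered, since the libraries of a group may be technical replicates. These splits take the PC3 libraries apart from their pairs. Among the 80 splits that part all 3 PC3 pairs, as the real one does, 1 reached 1735 and 2 reached 1667, and the highest other values were the same. The highest other values, 1667 and 1735, are each other's counts, since reversing the sort labels of 1 line turns the mean into the difference. Between the lines, 1 of 100 splits reached the 6256 genes of a model with 2 groups (highest other 5188), and a chance division of these libraries was excluded. For the absolute correlation between the lines' effects, 0.023, 97 of 100 splits were as large (highest other 0.60), and chance was not excluded, nor was it among the 40 splits that part the PC3 pairs (39 as large).

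In DU145, GC-rich genes were lower in GFP high. A GC bias of single libraries is a candidate explanation, because the libraries' GC correlation spread within a sort by 1.08 times the distance between the sorts (1.02 against 0.944), as DU145 GFP high replicate 3 lay with the GFP low libraries. Once the fitted trend was removed, 46.6% of the DU145 calls (1460 of 3133) were called in the same direction. This argues against the trend, as fitted here, as their whole source. The rest were not, and may depend on the trend. Unrelated sets of calls would also share some genes, and that share was not computed. Only GC content and length were removed, and both fits used the same libraries, so other bias of these libraries could keep calls. Whether part of the trend belongs to the sorted cells stays open.

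After removal of that trend, runs of 25 neighbouring genes were shifted beyond the 95th percentile of the largest run in 1000 shuffled gene orders. There were 9 such runs in DU145 and 12 in PC3. This argues only against the GC content and length of transcripts, as removed here, as their whole source. The GC content of the surrounding region was not removed, so GC bias was not excluded. Some runs lay close to the threshold, such as 1 on chromosome 14 in PC3 (median -0.1850, threshold 0.1845). The runs included 3 on chromosome 18 in DU145 (26225936 to 80033949 in GRCh38, medians 0.21 to 0.37), 3 on chromosome X in PC3 (276322 to 49175239, medians -0.32 to -0.22) and 6 on chromosome 14 in PC3 (medians -0.23 to -0.19). Genes below the minimum in the same runs, which had no part in finding them, shifted by 1.13 times the median of the tested genes. The 95% bootstrap interval was 0.858 to 1.30, with neighbouring genes taken as independent. A copy-number difference between the sorted populations would shift a whole region in this way. Genes below the minimum outside the runs were not compared, so a general shift of such genes was not excluded. Without a minimum and with the trend kept, the median over all genes went from -0.070 to 0.077 in DU145 and from -0.012 to -0.102 in PC3. PC3 GFP low replicates 2 and 3 had fewer genes at 0 counts than the other PC3 libraries. Whether this moved the PC3 median, or the genes below the minimum in the PC3 runs, was not tested. The agreement held for the pooled genes and not for every run. Genes below the minimum moved with the run in 17 of 21 runs. They moved against it in 4, on chromosomes 7 and 22 in DU145 and 8 and 17 in PC3. As a hypothesis, the sorts may differ in subclones of a line; regional regulation was not tested. The largest single-gene changes were mostly not shared by neighbouring genes. Up to 5 tested genes on either side of the 32 named genes of the lines moved by a median of 0.038 times the named gene's change (95% bootstrap interval -0.006 to 0.073). The ratio reached 0.477 at DSG2 on chromosome 18. Because the named genes were picked for their large changes, this ratio tends to be small. It argues only against a regional shift as large as the named change. A smaller regional part, or a copy-number change of 1 gene alone, was not excluded. For reads split with a near-identical copy, 23 of the 32 genes had whole estimated counts in all 12 libraries, which is 71.9% against the 80% set beforehand, so for the other 9 (USP3, HSPG2, HIST2H4A, CBSL, TIMP2, BTBD2, POLD4, AK4 and KDM4A) shared reads cannot be told apart from a change of the gene itself.

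CTNNA1 was detected in PC3, a line known for its deletion. DU145 cells or RNA in the PC3 libraries are argued against as the source, because CTNNA1 reached 86.3% of its DU145 level while 20 genes at 50 CPM or more in DU145 lay under 1% of that level in PC3, UCHL1 among them with 0 counts. Whether the PC3 libraries came from another line or a subline cannot be told apart from reads of a remaining part of the gene, since the values are summed per gene and hold no exons. The low counts of CDH1 and EPCAM in DU145 leave the same question open for that line. No biological explanation was tested.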

How the results depend on the processing

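Among the alternative fits of the named genes, 2 gave a call against the direction first estimated, while values that passed in neither fit could change sign. ALDH1A1, whose difference between lines was not called, had a called difference of 1.12 with an offset of 8 counts, and CTNNB1 in DU145 had a called -0.19 with the GC and length trend removed and the replicate block. The ribosomal list in DU145 turned upward without GFP high replicates 1 and 2 (adjusted p = 0.397). Apart from these, 5589 gene values stayed on the same side of the threshold, 181 lost the call and 73 gained it; of the list values 336 kept theirs, 46 lost it and 9 gained it. XPO4, USP3 and HSPG2 in DU145 kept their calls under every alternative. FN1 in DU145 kept its call under each alternative in which it was tested, the stricter expression minimum having dropped it. The causes were not tested except where fewer genes or samples, or a stricter threshold, lower a count by construction.

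Genes called in DU145 (3133) numbered 149 with a 2-fold threshold, 790 at an adjusted p under 0.01, 1949 with a minimum of 6, 1659 with quantile normalization, 6649 with arrayWeights, 126 without DU145 GFP high replicates 1 and 2, and 865 to 4928 when single libraries were left out. In PC3 (867) they numbered 126 with a 2-fold threshold, 372 at an adjusted p under 0.01, 506 with a minimum of 6, 4544 with arrayWeights, 2082 with the GC and length trend removed, 2334 with the replicate block added to that, 252 without PC3 GFP low replicates 2 and 3, and 462 to 1164 with single libraries left out. For the mean (1735) the counts were 54 with a 2-fold threshold, 471 at 0.01, 1153 with a minimum of 6, 6232 with arrayWeights, 541 without the 2 PC3 libraries, 272 without the 2 DU145 libraries and 726 to 3958 with single libraries left out. For the difference (1667) they were 294, 610, 1086, 6279, 1043 and 549 in that order, 2526 with the trend removed, 2996 with the block added to that, and 948 to 3207 with single libraries left out. Between the lines (6849) the count was 10801 without a minimum and 6572 to 6945 with single libraries left out. The weights of arrayWeights did not converge. The correlation between lines ranged from -0.20 to 0.18 with single libraries left out.

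Fry tests a list against no change and camera against the other genes, so their counts answer different questions. Lists called in DU145 (4) numbered 0 with an estimated correlation, 18 with fry in 1 direction, 22 with fry in either direction, 7 without a minimum, 7 with the trend removed and the replicate block, 2 without DU145 GFP high replicates 1 and 2, and 3 to 5 with single DU145 libraries left out. In PC3 (9) they numbered 1 with an estimated correlation, 19 with fry in either direction, 5 without PC3 GFP low replicates 2 and 3, and 5 to 12 with single PC3 libraries left out.

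With the replicate block, 1247 genes passed in PC3 and 6 lists, and apart from the TGF-beta, Notch and luminal lists it ended no list call there. In DU145 the numbers did not pair the samples. Same-numbered libraries correlated at -0.21, 0.19 and 0.47, and not every library correlated best with its own number. The block gave 4298 genes in DU145, 3453 for the mean and 2920 for the difference. A larger pseudocount, fixed beforehand for values of the form log2(normalized count + 1), was not run, because the values do not have that form. Fits that left out 2 libraries of a group had a lone sample there, assumed to vary like the other groups. Depth limited LEF1, AXIN2, LGR5 and other genes of few counts.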

Other observations

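Lists that were not called in either line also held genes that passed by themselves. Of 9 mesenchymal markers, 3 rose and 3 fell in DU145 and 3 rose and 2 fell in PC3. Of 9 basal epithelial markers, 1 rose and 2 fell in DU145 and 1 rose and 4 fell in PC3, and of 6 stem cell markers, 1 rose and 3 fell in DU145 and 1 rose and 1 fell in PC3. YAP targets (19) had 6 rises and 2 falls in DU145 and 5 rises and 3 falls in PC3. Of 20 immediate early genes, 3 rose and 6 fell in DU145 and 2 fell in PC3, and of 21 unfolded protein response genes, 3 rose and 6 fell in DU145 and 2 fell in PC3. Oxidative phosphorylation genes (34) had 2 rises and 6 falls in DU145 and 1 fall in PC3. Of 20 p53 targets, 4 rose and 2 fell in DU145 and 1 rose and 1 fell in PC3. Of 9 interferon response genes, 2 rose in DU145 and 1 rose and 1 fell in PC3. Androgen receptor targets (6) had 2 falls in DU145 and 1 rise and 1 fall in PC3, and neuroendocrine markers (4) had 2 falls in DU145. Hedgehog targets (3) had 1 rise and 1 fall in DU145. Of 14 housekeeping genes, 1 rose and 4 fell in DU145 and 1 rose in PC3.

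Some lists called in 1 line also held changed genes in the other. In DU145, 12 of 51 G2 and M phase genes rose and 11 fell, and of 16 NF-kB and inflammatory genes 2 rose and 6 fell. Fibroblast and stromal, endothelial and leukocyte markers had 1, 2 and 1 genes above the minimum, and Wnt ligands 1.

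PC3 GFP low replicates 2 and 3 had 3495 and 3491 genes at 0 counts, against 4577 to 4819 in the other PC3 libraries. A second tally gave 3506 in both, against 4577 to 4821. Greater depth does not account for this. Their total estimated counts were 17974060 and 15499672, against 16520446 to 21528810 in the other PC3 libraries. The cause, and its effect on PC3 genes of few counts, was not tested. The PC3 log2 fold change of TLE2 ranged from -3.45 to -1.18 over the alternatives, leaving out both libraries included.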
